A study of Mus musculus with 12 samples.

How the data were processed

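RNA abundance was measured on 12 Affymetrix arrays hybridised with labelled material from mouse ES cells of the D3 line. The labels place the arrays in 4 groups of 3: control day0, control day8, BPA day8 and NP day8. The labels do not spell out the agents BPA and NP and give no doses.

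The deposited values are log2 signals per probe set, made by the authors with MAS5, whose version and scaling target the labels do not state. On every array the mean of the back-transformed signals without the top and bottom 2% was 100.0, which shows that each array had been scaled to a common trimmed mean. The table held 45101 probe sets, of which 64 were control probe sets, and it held no detection calls. The number of arrays limits the precision of every value.

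Probe sets were named with the gene table of the array platform. It listed 35890 of the probe sets, 34958 of them with 1 gene and 932 with several, while 9211 were not listed. Of those with 1 gene, 34754 matched a RefSeq gene by Entrez identifier in the table for assembly GRCm38.p6, and 0 symbols changed. No genome positions are given, since the build behind the array annotation was not named.

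Values were used as deposited, with no pseudocount and no further scaling between arrays. The 60% of probe sets with the highest mean over the 12 arrays were kept, which left 27023. Control probe sets were left out, and each gene was represented by its probe set with the highest mean, which left 13067 genes. A linear model with a mean per group was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (8 residual and 1.57 prior degrees of freedom). Tests were 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. The 4 comparisons were control day8 against control day0, each agent against control day8, and NP day8 against BPA day8.

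Gene lists were tested with camera in limma, 2-sided, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Of 43 lists, 42 had at least 5 measured members and were tested, and the remaining list had 2 measured members. The lists held 975 genes, of which 762 were tested. Each list was also tested with an estimated correlation, and its mean on each array was compared between groups by an exact permutation test, 2-sided, whose smallest possible p is 0.1 for 3 arrays against 3. The position of an array between the control groups was the list mean scaled to 0% at control day0 and 100% at control day8.

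The groups, comparisons, filter, tests, gene lists, the rule for naming genes and all alternatives except the background floor were fixed before the data were examined. The rule named, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group lay at or above the median gene mean of 6.55, up to 2 members of each list per direction, and a fixed set of marker genes. Where fewer than 10 genes passed, it named all of them and the 10 with the smallest p.

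A background level was taken after the data were seen from 3 bacterial control probe sets (TrpnX) on 12 arrays. Their highest value of 36 was a log2 signal of 3.41, a signal of 10.6. Where all 3 arrays of a group lay under this level, the fold was computed against the level and is given as a lower bound. Where the mean of a group lay under it but not every array, each value under the level was set to it and the change of a gene called is given as at least that size.

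The alternatives were 2 pseudocounts, other filters, quantile normalization, median centring, other choices of probe set, other variance priors, array weights, only the compared groups in the fit, the replicate number as a block, a fold threshold of 2, control arrays split between the agents, and each of the 12 arrays left out in turn. Overlap between the responses to the agents was set beside 50 draws of simulated unchanged groups that shared their controls. The method was tested on simulated data in which 100 genes were shifted by each size. A log2 shift of 1 was recovered for 47.0% of the genes in control day8 against control day0, 51.0% with BPA, 52.0% with NP and 49.0% in NP against BPA. A log2 shift of 2 was recovered for 84.0%, 78.0%, 84.0% and 67.0%. Of the genes that were not shifted, 8, 15, 8 and 9 were called in turn. Far fewer genes were shifted than were called in the comparisons with a control group, which makes the adjustment stricter. For those comparisons the recovery given may therefore be too low. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out of the values given.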

Results

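RNA from mouse ES cells of the D3 line, an embryonic stem cell line, was measured on 12 arrays in 4 groups of 3. The cells had been grown on a feeder layer of mouse embryonic fibroblasts treated with MMC and differentiated as embryoid bodies, aggregates in which stem cells form derivatives of the germ layers. Control arrays were taken at day 0 and day 8 without an agent, and the treated arrays at day 8 with the agent labelled BPA or the agent labelled NP. The series concerns the effect of chemicals on ES cell differentiation. The labels give no doses and do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. Values are log2 signals, and errors of changes are standard errors from the model with 3 arrays per group. On average 59.7% of probe sets lay above the background level on control day0 arrays, 61.4% on control day8, 60.7% on BPA day8 and 60.4% on NP day8.

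Between day 0 and day 8 of control culture, genes of the pluripotent state fell and genes of yolk sac endoderm, heart muscle and blood vessels rose. As lists they did not stay past the threshold with an estimated correlation (adjusted p = 0.201 for pluripotency, 0.114 for visceral and primitive endoderm, 0.313 for cardiac muscle and 0.114 for vascular endothelium). Pou5f1, the central transcription factor of the pluripotent state, went from 11.45 ± 0.12 (SD, n = 3) to 7.65 ± 0.84, a log2 change of -3.80 ± 0.38. Nanog (-2.80 ± 0.28), Zfp42 (-3.60 ± 0.22) and Esrrb (-3.36 ± 0.20), further transcription factors of naive pluripotent cells, fell with it. Afp, a fetal serum protein of yolk sac and liver, was at least 231-fold higher at day 8, and Ttr, a carrier of thyroid hormone and retinol, at least 366-fold. Their day 0 means lay under the background level. Tnnt2, a troponin of the cardiac sarcomere, was at least 44.4-fold higher, and Myh6, the atrial myosin heavy chain, rose by 2.65 ± 0.44. Sox2, a partner of Pou5f1, fell by 1.68 ± 0.15.

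This first comparison asked what changes over differentiation without an agent. Of 13067 genes tested, 6365 changed, 3692 higher and 2673 lower at day 8, and 3003 of them by at least 2-fold. The 2 groups of arrays did not overlap for 7419 genes (56.8%), where chance gives 10%. Large rises included S100g, a calcium-binding protein (at least 53.6-fold), Tnni1, the slow skeletal troponin (at least 31.6-fold), and Hba-x, an embryonic globin (at least 16.3-fold). Tmprss2, a serine protease, rose by at least 4.69 and Cited1, a transcriptional coactivator, by at least 5.24. Large falls were those of Ifi202b (by at least 3.72), Pla2g1b, a phospholipase (by at least 4.17), Mmp3, a matrix metalloprotease (by at least 3.53), Mymx, a micropeptide of myoblast fusion (-5.24 ± 0.47), and Mgp, a matrix protein (-5.22 ± 0.47). Platr10, a noncoding RNA, was at least 13.7-fold lower and Ereg, a growth factor, at least 11.7-fold. The cells had been grown on feeder fibroblasts. For genes that feeder cells also express, loss of feeder RNA and a fall in the ES cells cannot be told apart. The split between higher and lower depended on scaling: 58.0% of calls were higher with the deposited values, 47.4% after quantile normalization and 36.4% after centring each array on its median. The median change over all tested genes was 0.12, -0.06 and -0.19 in turn.

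Of the 32 measured members of the pluripotency list, 31 fell (31 adjusted over the list alone), with a median of -2.72 (adjusted p = 2.03e-19, and 0.201 with an estimated correlation). Lin28a, an RNA-binding protein of stem cells, did not pass, at -0.17. The largest fall in the list was that of Nr0b1, a nuclear receptor (-5.17 ± 0.42), followed by Lefty1, an inhibitor of Nodal signals (-4.40 ± 0.27). Germ cell genes had 9 of 14 members lower and 1 higher (10 and 1 adjusted over the list alone, median -1.34, and -0.99 with bounds, adjusted p = 0.00327, and 0.313 with an estimated correlation), among them Ddx4, an RNA helicase of germ cells (-2.28 ± 0.23). Of the genes for DNA methylation and chromatin, 15 of 25 fell and 2 rose (the same counts adjusted over the list alone, median -0.52, adjusted p = 5.81e-05, and 0.201 with an estimated correlation). Tet1, which oxidises methylcytosine, fell by 3.30 ± 0.22, while Bmi1, a Polycomb protein, rose by 1.72 ± 0.11. Cell cycle genes had 19 of 39 members lower and 4 higher (the same adjusted over the list alone, median -0.34, adjusted p = 0.000254, and 0.262 with an estimated correlation). Ccne1, a cyclin of entry into DNA replication, was at -2.52 ± 0.16.

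Genes of visceral and primitive endoderm, the lineages of the yolk sac, had 30 of 33 members higher and 1 lower (31 and 1 adjusted over the list alone, median 4.53, and 3.82 with bounds, adjusted p = 4.44e-14, and 0.114 with an estimated correlation). Gata6, a transcription factor of endoderm, rose by 4.25 ± 0.20, Sox17 by at least 5.30 and Gata4 by at least 2.01, the last 2 with day 0 means under the background level. Of the definitive endoderm and gut genes 13 of 16 rose and 2 fell (the same adjusted over the list alone, median 3.18, and 2.42 with bounds, adjusted p = 0.00105, and 0.313 with an estimated correlation), with Krt19, a keratin of simple epithelia, at 5.29 ± 0.34. In the cardiac muscle list 20 of 29 rose and 1 fell (21 and 1 adjusted over the list alone, median 2.77, and 2.66 with bounds, adjusted p = 1.91e-05, and 0.313 with an estimated correlation). Hand2 and Tbx20, transcription factors of the developing heart, were higher by at least 86.5-fold and by at least 5.27 on the log2 scale. The member that fell, the calcium pump Atp2a2, was at -0.38 ± 0.08 on its chosen probe set and at 0.22 as the mean of its probe sets. Vascular endothelium genes had 16 of 21 members higher and 0 lower by limma (the same adjusted over the list alone, median 1.99, and 1.98 with bounds, adjusted p = 7.63e-05, and 0.114 with an estimated correlation), with Kdr, the main receptor for vascular growth factor, at 3.68 ± 0.44. Trophoblast genes rose for 8 of 11 members (8 adjusted over the list alone, median 3.58, and 3.40 with bounds, adjusted p = 0.00478, and 0.313 with an estimated correlation). Hbb-bh1, an embryonic globin, rose by at least 5.86 (adjusted p = 0.0326), and its call ended when any 1 of the 6 control arrays was left out (adjusted p up to 0.0862).

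Imprinted genes rose for 17 of 26 members and fell for 3 (18 and 3 adjusted over the list alone, median 1.66, adjusted p = 0.00019, and 0.313 with an estimated correlation), with Dlk1, a Notch-like ligand, at 5.89 ± 0.46. Glycolysis and hypoxia genes had 19 of 31 members higher and 3 lower (the same adjusted over the list alone, median 0.66, adjusted p = 0.00608, and 0.586 with an estimated correlation). Fibroblast and matrix genes, which the feeder cells also express, had 20 of 34 members lower and 6 higher (21 and 6 adjusted over the list alone, median -1.25, adjusted p = 0.00134, and 0.337 with an estimated correlation). S100a4, a calcium-binding protein of fibroblasts, fell by at least 6.67 and Thy1, a surface glycoprotein, by at least 4.56, whereas Twist1, a mesenchymal transcription factor, rose by 3.52 ± 0.37 and Lum, a matrix proteoglycan, by 2.94 ± 0.30. The list of NRF2 oxidative stress genes had 12 of 19 members lower and 3 higher (13 and 3 adjusted over the list alone, median -0.93, adjusted p = 0.000356, and 0.337 with an estimated correlation), with Gsta4, a glutathione transferase, at -2.25 ± 0.14. Fgf5, a marker of primed epiblast, was at -1.07 ± 0.30, Pax6, a neural transcription factor, at -1.44 ± 0.37, and Tubb3, a neuronal tubulin, at -2.47 ± 0.34, and all 3 passed. Nes (-0.33, adjusted p = 0.269) and Col1a1 (0.50, adjusted p = 0.271) did not pass. Each of the markers and list members above that is written as changed, apart from Hbb-bh1, passed with every array left out in turn.

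The lists for retinoid pathway, oxidative phosphorylation, ribosomal proteins and immediate early genes also passed, but their calls ended without single arrays. For the retinoid pathway 7 of 12 members rose and 1 fell (the same adjusted over the list alone, median 1.89, adjusted p = 0.031, and 0.561 with an estimated correlation), and without control day8 replicate 2 the adjusted p was 0.0504. Oxidative phosphorylation genes had 11 of 36 members lower (9 adjusted over the list alone, median -0.14, adjusted p = 0.0117, and 0.586 with an estimated correlation), with an adjusted p of 0.0812 without control day8 replicate 2 and 0.948 after quantile normalization. Ribosomal protein genes had 4 of 30 members lower and 1 higher (0 of either adjusted over the list alone by limma; median -0.11, adjusted p = 0.0258, and 0.699 with an estimated correlation). Their adjusted p was 0.066 without control day0 replicate 3, 0.0884 without control day8 replicate 2 and 0.948 after quantile normalization. Immediate early genes had 8 of 21 members lower and 3 higher (the same adjusted over the list alone, median -0.76, adjusted p = 0.0331, and 0.586 with an estimated correlation). Their adjusted p was 0.0875 without control day0 replicate 3, 0.0517 without control day8 replicate 3, 0.108 after quantile normalization and 0.0771 after median centring.

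**Figure D1:**
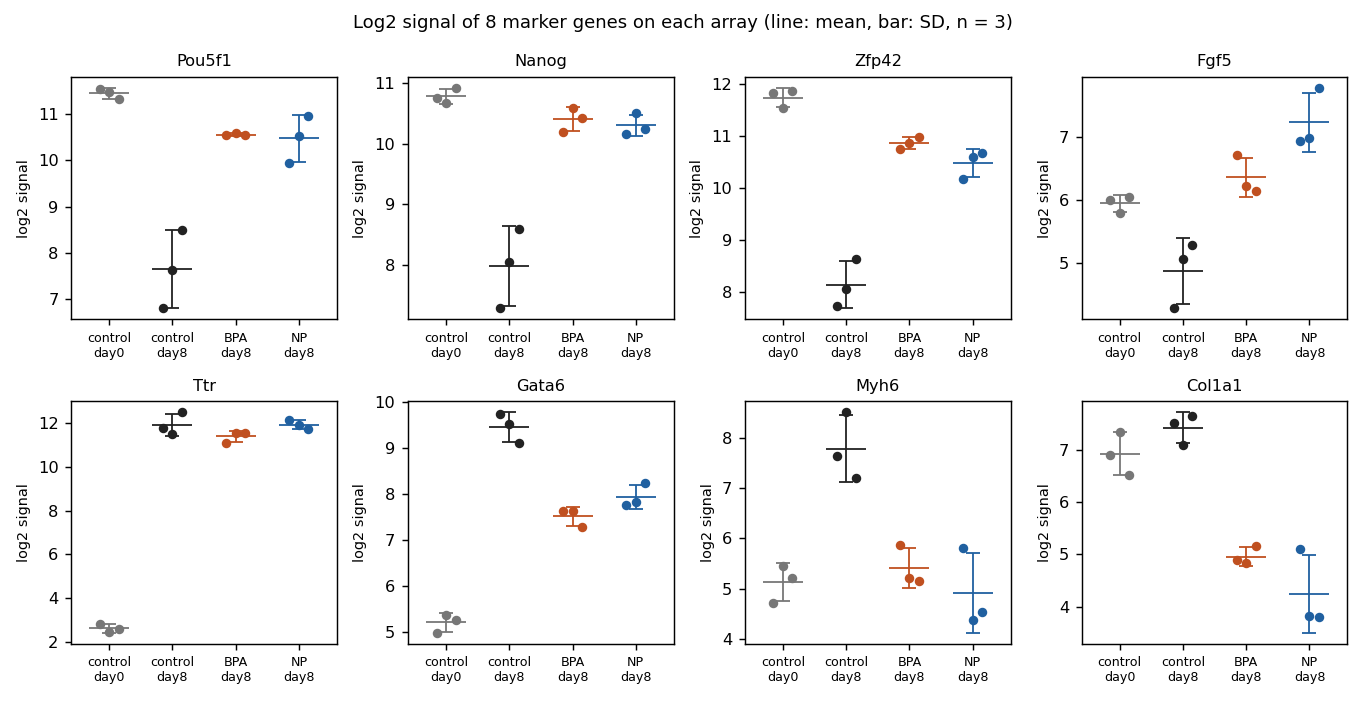
Log2 signal of 8 marker genes on each of the 12 arrays (vertical axis) by group (horizontal axis); points are arrays, the line is the mean and the bar the SD of 3 arrays. Pou5f1 lay at 11.45 on control day0, 7.65 on control day8, 10.56 on BPA day8 and 10.48 on NP day8 arrays.

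With BPA, day 8 arrays carried more RNA of pluripotency genes and less of heart, vessel and connective tissue genes than control day8 arrays, while yolk sac endoderm markers did not pass as a group. With an estimated correlation 0 lists passed by camera (adjusted p = 0.142 for pluripotency, 0.257 for cardiac muscle, 0.0725 for vascular endothelium and 0.0725 for fibroblast and matrix genes). Pou5f1 was at 10.56 ± 0.03 (SD, n = 3) with BPA and 7.65 ± 0.84 without, a log2 change of 2.92 ± 0.38 (adjusted p = 0.000998). Nanog (2.42 ± 0.28), Zfp42 (2.73 ± 0.22), Esrrb (2.16 ± 0.20) and Sox2 (1.51 ± 0.15) rose as well. Myl7, the atrial myosin light chain, fell by 4.38 ± 0.88 and Hand2 by 4.72 ± 0.73. Postn, a matrix protein of connective tissue (-5.19 ± 0.32), and the collagens Col3a1 (-4.64 ± 0.33) and Col5a2 (-4.36 ± 0.39) were among the largest falls.

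The comparison asked for the effect of the agent labelled BPA at day 8. Of 13067 genes, 2906 changed, 1569 higher and 1337 lower, and 1199 by at least 2-fold. Without control day8 replicate 1 the count was 1822. The arrays of the groups did not overlap for 41.6% of genes, where chance gives 10%. The largest rises beside pluripotency genes included Mymx (4.45 ± 0.47), Mt4, a metallothionein (at least 2.78), Hsf2bp, a meiotic protein (3.35 ± 0.51), and Cbr3, a carbonyl reductase (3.31 ± 0.28). Ctsj, a placental cathepsin (at least 2.77), Zfp979, a zinc finger gene (3.26 ± 0.26), and Triml1 (3.23 ± 0.22) rose as well. Among the falls were Lum (-4.56 ± 0.30), Ccdc80, a matrix protein (by at least 3.33), and Pgam2, the muscle phosphoglycerate mutase, at least 9.41-fold lower. Smc1b, a meiotic cohesin subunit (3.31 ± 1.02, adjusted p = 0.0447), lost its call when control day0 replicate 2, control day8 replicate 1 or any BPA or NP array was left out (adjusted p up to 0.104). Frem1, a basement membrane protein (lower by at least 2.98), lost its call without control day8 replicate 1 (adjusted p = 0.0509).

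In the pluripotency list 30 of 32 members rose and 0 fell by limma (30 and 1 adjusted over the list alone, median 1.96, adjusted p = 2.44e-20, and 0.142 with an estimated correlation). The members with the largest rises were Dppa2, a chromatin factor of pluripotent cells (3.72 ± 0.34), and Fgf4, a growth factor made by them (3.24 ± 0.39). The list mean was 9.01 ± 0.04 (SD, n = 3) on BPA arrays, 7.05 ± 0.42 on control day8 and 9.76 ± 0.03 on control day0 arrays. Germ cell genes rose for 10 of 14 members (11 adjusted over the list alone, median 1.70, and 1.59 with bounds, adjusted p = 1.99e-06, and 0.142 with an estimated correlation), including Dazl, an RNA-binding protein of germ cells (2.90 ± 0.28). The pluripotency list shares 2 of these 14 genes, Prdm14 and Dppa3. Genes for DNA methylation and chromatin had 13 of 25 members higher and 2 lower (the same adjusted over the list alone, median 0.31, adjusted p = 0.000949, and 0.257 with an estimated correlation), with Dnmt3l, a cofactor of the de novo methyltransferases, at 2.92 ± 0.39. The other direction held for Bmi1 (-0.84 ± 0.11), and for Smarcc1 (-0.46 ± 0.13) only on its chosen probe set: the mean of its probe sets was 0.14, and its call ended when control day8 replicate 1 or 2 or any BPA array was left out (adjusted p up to 0.108). The NRF2 list had 11 of 19 members higher and 1 lower (the same adjusted over the list alone, median 0.65, adjusted p = 4.38e-05, and 0.3 with an estimated correlation), with Ephx1, an epoxide hydrolase, at 1.79 ± 0.39 and Gsta4 at 1.60 ± 0.14. Interferon response genes rose for 8 of 20 members and fell for 1 (10 and 1 adjusted over the list alone, median 0.98, adjusted p = 0.00133, and 0.3 with an estimated correlation), with Psmb8, a subunit of the immunoproteasome, at 2.38 ± 0.43.

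Cardiac muscle genes fell for 17 of 29 members and rose for 0 by limma (19 and 0 adjusted over the list alone, median -2.37, adjusted p = 2.93e-07, and 0.257 with an estimated correlation), with Myh6 at -2.37 ± 0.44. Tnnt2 was at -4.11 ± 1.02 (adjusted p = 0.0189), and its call ended without control day8 replicate 1 or 2 or BPA day8 replicate 2 or 3 (adjusted p up to 0.0612). Tnni1 was at -4.53 ± 1.37 (adjusted p = 0.0414) and lost its call when any control or BPA array was left out (adjusted p up to 0.112). Vascular endothelium genes fell for 11 of 21 members (13 adjusted over the list alone, median -1.23, adjusted p = 1.23e-05, and 0.0725 with an estimated correlation), with Kdr at -2.94 ± 0.44. Smooth muscle genes fell for 6 of 12 (9 adjusted over the list alone, median -1.20, adjusted p = 0.00021, and 0.257 with an estimated correlation), with Acta2, smooth muscle actin, at -2.65 ± 0.45. Of the fibroblast and matrix genes 24 of 34 fell and 1 rose (the same adjusted over the list alone, median -1.86, adjusted p = 2.83e-15, and 0.0725 with an estimated correlation), and Col1a1 was at -2.47 ± 0.35. Imprinted genes fell for 11 of 26 members and rose for 1 (12 and 2 adjusted over the list alone, median -0.76, adjusted p = 2.42e-05, and 0.257 with an estimated correlation), with Dlk1 at -3.80 ± 0.46. The Wnt target and cell cycle lists passed with calls that ended without single arrays. Wnt target genes had 3 of 12 lower and 1 higher (4 and 1 adjusted over the list alone, median -0.78, and -0.71 with bounds, adjusted p = 0.0283, and 0.3 with an estimated correlation), and the adjusted p was 0.074 without control day8 replicate 1, 0.0639 without control day8 replicate 2 and 0.0505 without BPA day8 replicate 3. Cell cycle genes had 8 of 39 higher (8 adjusted over the list alone, median 0.10, adjusted p = 0.0448, and 0.388 with an estimated correlation), and the call ended when control day0 replicate 2, any control day8 array, or BPA day8 replicate 1 or 2 was left out (adjusted p up to 0.102). It also ended after quantile normalization (adjusted p = 0.103), without _s_at and _x_at probe sets (0.0751), with only the compared groups in the fit (0.0627), with a pseudocount at the 50th percentile (0.0521) and with values under the background level set to it (0.0598).

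In the visceral and primitive endoderm list 1 of 33 members rose and 2 fell (the same adjusted over the list alone, median -0.30, adjusted p = 0.143). The definitive endoderm and gut list did not pass either, with 2 of 16 higher and 3 lower (the same adjusted over the list alone, median -0.35, adjusted p = 0.208), but its mean was lower by 0.77 with the arrays apart (exact permutation p = 0.1, the smallest possible). Rhox5, a homeobox gene of extraembryonic tissue, rose by 1.95 ± 0.22, and Gata6 fell by 1.94 ± 0.20. Afp (0.62, adjusted p = 0.59), Ttr (-0.52, adjusted p = 0.164), Sox17 (-0.10, adjusted p = 0.808) and Gata4 (-0.52, adjusted p = 0.641) did not pass. Fgf5 (1.49 ± 0.30) and Tubb3 (1.54 ± 0.34) rose, while Pax6 (-0.72, adjusted p = 0.206), Nes (-0.52, adjusted p = 0.136) and Hbb-bh1 (-5.10, adjusted p = 0.108) did not pass. With values under the background level set to it, Hbb-bh1 passed (-3.78, adjusted p = 0.0372). A sign of RNA integrity moved with the agent: the 3' minus 5' difference of the Actb probe sets was 1.61 ± 0.10 (SD, n = 3) with BPA and 1.34 ± 0.07 on control day8 arrays (exact permutation p = 0.1, the smallest possible). The same difference for Gapdh was higher by 0.095 with BPA, but the arrays overlapped (exact permutation p = 0.4).

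**Figure D2:**
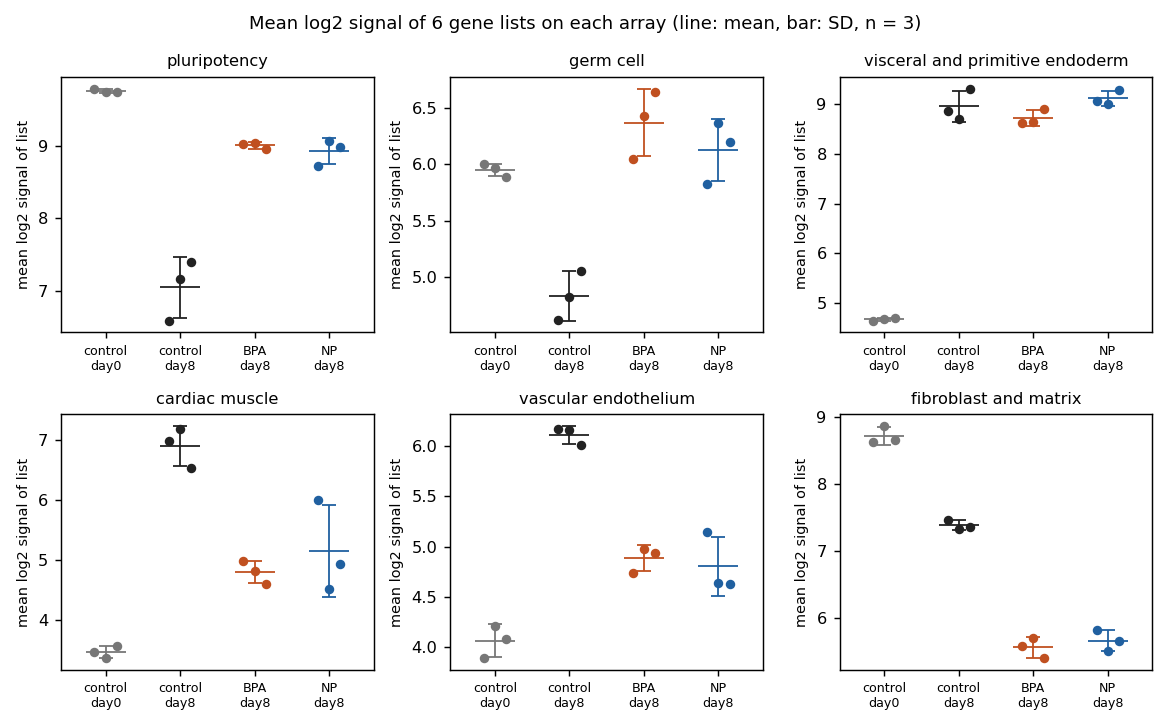
Mean log2 signal of 6 gene lists on each array (vertical axis) by group (horizontal axis); points are arrays, the line is the mean and the bar the SD of 3 arrays. The pluripotency list lay at 9.76 on control day0, 7.05 on control day8, 9.01 on BPA day8 and 8.93 on NP day8 arrays, and the visceral and primitive endoderm list at 4.67, 8.96, 8.73 and 9.12.

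With NP, pluripotency genes were again higher and heart, vessel and connective tissue genes lower than on control day8 arrays. With an estimated correlation the vascular endothelium and fibroblast and matrix lists passed (adjusted p = 0.0383 for each), and the pluripotency (0.102) and cardiac muscle (0.249) lists did not. Pou5f1 was at 10.48 ± 0.51 (SD, n = 3), a log2 change of 2.83 ± 0.38 (adjusted p = 0.00196). Nanog (2.32 ± 0.28), Zfp42 (2.35 ± 0.22), Esrrb (1.90 ± 0.20) and Sox2 (1.47 ± 0.15) rose too, and Fgf5 rose by 2.37 ± 0.30. Hand2 fell by 4.19 ± 0.73, Myh6 by 2.87 ± 0.44 and Kdr by 2.54 ± 0.44. Postn (-5.15 ± 0.32), Col3a1 (-4.96 ± 0.33) and Col1a1 (-3.18 ± 0.35) also fell.

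The comparison asked for the effect of the agent labelled NP at day 8. Of 13067 genes, 1852 changed, 1032 higher and 820 lower, and 764 by at least 2-fold. The arrays of the groups did not overlap for 34.8% of genes, where chance gives 10%. The count was 802 without control day8 replicate 1, 1022 without control day8 replicate 2, 854 without NP day8 replicate 2, 896 without NP day8 replicate 3, 645 when only the compared groups were in the fit and 1182 with no filter. Further large rises were those of Mymx (3.67 ± 0.47), Tdgf1, a Nodal coreceptor (3.25 ± 0.32), Eras, a Ras protein of ES cells (3.25 ± 0.26), and Dnmt3l (2.79 ± 0.39). Zfp979 (2.94 ± 0.26), Fgf4 (2.86 ± 0.39) and Triml1 (2.76 ± 0.22) rose as well. Falls included Lum (-4.07 ± 0.30), Col5a2 (-4.05 ± 0.39), Adam12, a metalloprotease (by at least 3.45), and Snai2, a transcription factor of mesenchymal transition (-3.57 ± 0.66).

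In the pluripotency list 30 of 32 members rose and 0 fell by limma (the same adjusted over the list alone, median 1.79, adjusted p = 4.69e-26, and 0.102 with an estimated correlation), led by Dppa2 (3.65 ± 0.34) and Nr0b1 (3.54 ± 0.42). Germ cell genes rose for 9 of 14 members (11 adjusted over the list alone, median 1.46, and 1.42 with bounds, adjusted p = 8.34e-07, and 0.107 with an estimated correlation), with Dazl at 2.73 ± 0.28 and Stra8, a gene of meiotic entry, at 2.65 ± 0.31. Primed epiblast genes had 6 of 12 members higher and 1 lower (the same adjusted over the list alone, median 1.09, and 0.78 with bounds, adjusted p = 0.00194, and 0.249 with an estimated correlation), with Pou3f1, a POU factor, at 2.03 ± 0.23, and without control day8 replicate 3 the adjusted p was 0.0605. With BPA the same list did not pass, with 5 of 12 members higher and 2 lower (7 and 2 adjusted over the list alone, median 0.83, adjusted p = 0.177), though the arrays lay apart from control day8 arrays for both agents (mean 7.08 with BPA, 7.37 with NP and 6.50 on control day8 arrays, exact permutation p = 0.1 for each). Genes for DNA methylation and chromatin had 11 of 25 higher and 1 lower (the same adjusted over the list alone, median 0.23, adjusted p = 0.000103, and 0.211 with an estimated correlation), with Phc1, a Polycomb protein, at 1.62 ± 0.12. The NRF2 list had 7 of 19 members higher (11 adjusted over the list alone, median 0.49, adjusted p = 7.32e-05, and 0.296 with an estimated correlation), with Gsta4 at 1.33 ± 0.14 and Srxn1, a sulfiredoxin, at 1.05 ± 0.18. Genes of endoplasmic reticulum stress and the amino acid response had 6 of 31 higher and 1 lower (10 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.000734, and 0.36 with an estimated correlation), with Slc7a3, a cationic amino acid transporter, at 2.17 ± 0.22. Of the 30 ribosomal protein genes 0 passed by limma, also when adjusted over the list alone, while the list passed (median 0.19, adjusted p = 7.65e-05, and 0.451 with an estimated correlation, adjusted p = 0.457 after quantile normalization). Cell cycle genes had 5 of 39 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.0242, and 0.441 with an estimated correlation), and the adjusted p was 0.0606 without control day8 replicate 1, 0.0557 without NP day8 replicate 2 and 0.1 after quantile normalization.

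Cardiac muscle genes fell for 13 of 29 members (18 adjusted over the list alone, median -1.87, adjusted p = 1.03e-06, and 0.249 with an estimated correlation). NP day8 replicate 1 lay nearer to control day8 arrays, since its list mean was at 73.8% of the way from control day0 to control day8, while replicate 2 was at 30.8%. Over all genes replicate 1 correlated with the control day8 mean by 0.945, against 0.926 and 0.915 for replicates 2 and 3. Tnnt2 (-3.73 ± 1.02, adjusted p = 0.0403) lost its call when control day0 replicate 3, any control day8 or BPA array, or NP day8 replicate 2 or 3 was left out (adjusted p up to 0.12). Tnni1 (-4.96 ± 1.37, adjusted p = 0.0411) lost it when any control or BPA array or NP day8 replicate 3 was left out (adjusted p up to 0.116). Hba-x (lower by at least 3.36, adjusted p = 0.0413), lost it when any control array, BPA day8 replicate 1, or NP day8 replicate 2 or 3 was left out (adjusted p up to 0.131). Vascular endothelium genes fell for 8 of 21 members (12 adjusted over the list alone, median -1.06, adjusted p = 1.02e-07), and fibroblast and matrix genes for 22 of 34 (27 lower and 2 higher adjusted over the list alone, median -1.68, adjusted p = 1.63e-16). These lists kept their call with an estimated correlation, each with an adjusted p of 0.0383. Smooth muscle genes fell for 5 of 12 (7 adjusted over the list alone, median -0.77, adjusted p = 0.000145, and 0.249 with an estimated correlation), with Acta2 at -2.40 ± 0.45. Imprinted genes fell for 11 of 26 and rose for 1 (13 and 1 adjusted over the list alone, median -0.55, adjusted p = 0.000199, and 0.274 with an estimated correlation). Cholesterol synthesis genes fell for 6 of 19 members (11 adjusted over the list alone, median -0.43, adjusted p = 0.000117, and 0.45 with an estimated correlation). Of 14 Hox genes 0 passed by limma, also when adjusted over the list alone, while the list passed (median -1.04, and -0.87 with bounds, adjusted p = 0.0376, and 0.441 with an estimated correlation). The NP and control day8 arrays overlapped for this list (exact permutation p = 0.2). Its call ended without control day8 replicate 1 (adjusted p = 0.103), control day8 replicate 3 (0.139), NP day8 replicate 1 (0.0813) or NP day8 replicate 2 (0.0557).

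Visceral and primitive endoderm genes rose for 3 of 33 members and fell for 2 (the same adjusted over the list alone, median 0.13, adjusted p = 0.457), with Rhox5 at 1.29 ± 0.22 and Gata6 at -1.51 ± 0.20. Afp (1.16, adjusted p = 0.33), Ttr (0.01, adjusted p = 0.988), Sox17 (0.38, adjusted p = 0.352), Gata4 (-0.41, adjusted p = 0.75), Pax6 (0.53, adjusted p = 0.398), Nes (0.06, adjusted p = 0.897) and Hbb-bh1 (-4.90, adjusted p = 0.153) did not pass. With values under the background level set to it, Afp (1.16, adjusted p = 0.0154) and Hbb-bh1 (-4.24, adjusted p = 0.0316) passed. For Afp every NP array lay above every control day8 array. Tubb3 (1.17 ± 0.34, adjusted p = 0.0457) lost its call with any of the 12 arrays left out (adjusted p up to 0.145). The 3' minus 5' difference of the Actb probe sets was 1.55 ± 0.09 (SD, n = 3) with NP and 1.34 ± 0.07 on control day8 arrays (exact permutation p = 0.1, the smallest possible).

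The responses to the agents overlapped. Of the genes called with NP, 1586 (85.6%) were called with BPA in the same direction, 908 higher and 678 lower, and 0 in opposite directions by limma, where independent lists of these sizes would share 124 and 84 and oppose in 204. Across genes, which are not independent replicates, the changes correlated with r = 0.833. The comparisons share their control arrays, and simulated unchanged groups gave a mean r of 0.517 (range 0.120 to 0.915). When each agent was set against different control arrays r was 0.495 to 0.594. The covariance was 0.520, against 0.020 to 0.192 in the simulations, and 0.363 to 0.456 with split controls. Neither the simulations nor the splits cover an offset common to all control day8 arrays. The overlap count was 730 without control day8 replicate 1, 917 without control day8 replicate 2, 777 without NP day8 replicate 2 and 845 without NP day8 replicate 3. It was 564 with only the compared groups in each fit, 1014 with no filter and 652 with a fold threshold of 2.

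**Figure D3:**
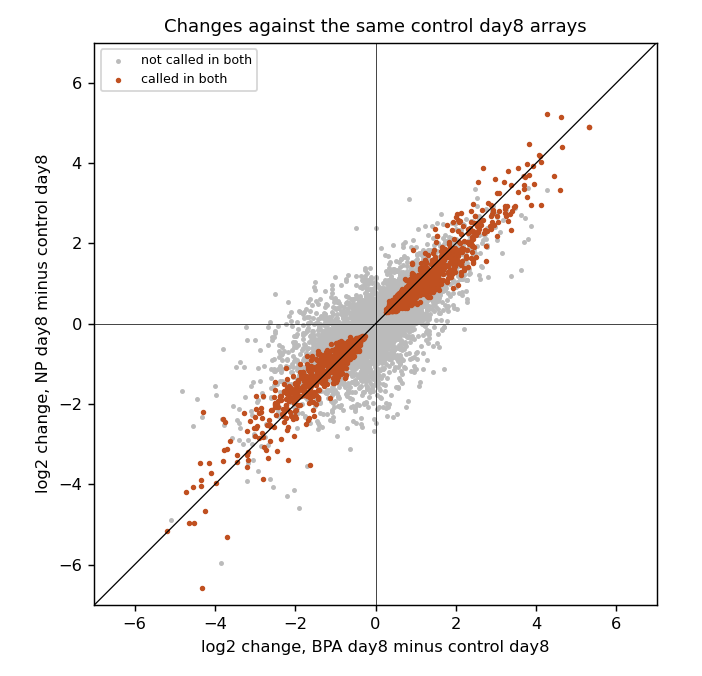
Log2 change with NP (vertical axis) against log2 change with BPA (horizontal axis), both relative to the same control day8 arrays; each point is 1 of 13067 genes, those called in both are coloured and the diagonal marks equal change. The 1586 coloured points lie in the quadrants of equal sign.

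Most genes called with an agent had moved the other way in the controls. Of the 2329 genes called with BPA and over control differentiation, 2208 went in opposite directions, where independent lists would give 699, and of 1588 such genes with NP, 1532 did, against 443. The shared control day8 arrays alone give part of this. The covariance was -0.611 with BPA, against a mean of -0.133 for simulated unchanged groups, and -0.549 with NP, against -0.126, whereas r across genes was -0.595 with BPA, against a mean of -0.564 for simulated unchanged groups, and -0.596 with NP, against -0.541. With control arrays split between the comparisons it was -0.497 to -0.388 with BPA and -0.481 to -0.384 with NP. Here too an offset common to all control day8 arrays was not covered.

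On a scale from 0% at control day0 to 100% at control day8, the pluripotency list lay at 27.7% ± 1.6 (SD, n = 3) with BPA and 30.8% ± 6.6 with NP. The cardiac muscle list lay at 38.8% ± 5.5 with BPA and 49.1% ± 22.2 with NP. Visceral and primitive endoderm genes lay at 94.5% ± 3.7 with BPA and 103.7% ± 3.6 with NP, and definitive endoderm and gut genes at 72.2% ± 3.9 and 86.5% ± 13.9. These positions are on the log2 scale, over control spans of -2.71 for pluripotency and 4.29 for visceral and primitive endoderm. They are not shares of cells and cannot be compared directly between lists. A mixture with 49.3% to 51.1% of day0 signal on BPA arrays predicted a median change of only -0.95 for visceral endoderm genes. Part of the contrast between the lists can therefore come from the scale. For the pluripotency and cardiac lists the arrays of each agent lay apart from control day8 arrays (exact permutation p = 0.1, the smallest possible), and for the visceral and primitive endoderm list they did not (exact permutation p = 0.3 with BPA and 0.5 with NP).

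The direct comparison asked whether the agents differ from each other at day 8, at doses the labels do not give and that cannot be matched. Tgfb3, a growth factor of the transforming growth factor family, was the 1 gene of 13067 that passed, at 3.70 ± 0.16 (SD, n = 3) with NP and 0.56 ± 0.70 with BPA (log2 change 3.14 ± 0.33, adjusted p = 0.0425). The BPA mean lay under the background level, so the rise is bounded only at 1.23-fold. With values under that level set to it the difference was 0.30 (adjusted p = 0.682), and the call ended when any array other than control day0 replicate 2 and BPA day8 replicates 2 and 3 was left out (adjusted p up to 0.188). Next by p came St8sia1, a sialyltransferase (-1.05 ± 0.13, adjusted p = 0.0746), Srebf2, the regulator of cholesterol synthesis (-0.64 ± 0.11), Fads3 (-1.24 with values under the background level set to it), Pltp, a phospholipid transfer protein (-0.68 ± 0.12), Sesn2, a stress-induced sestrin (0.89 ± 0.16), Tbc1d12 (0.71 ± 0.13) and Herpud1, of the endoplasmic reticulum stress response (0.64 ± 0.11), the last 6 each at an adjusted p of 0.277. Pde7b and Fbln5 had a group mean or both group means under the background level. At an unadjusted threshold 1095 genes passed, where chance gives 653 on average, and the arrays did not overlap for 17.0% of genes, where chance gives 10% on average. Genes vary together, so such counts can lie well away from these averages, and the excess does not show that the agents differ. The 95% interval of the difference had a median width of 0.90 log2 units and lay wholly within 1 log2 unit of 0 for 8950 genes (68.5%). Pou5f1 differed by -0.08 (95% interval -0.93 to 0.76), Nanog by -0.11, Sox2 by -0.04 and Fgf5 by 0.88 (adjusted p = 0.488).

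As groups, 11 lists differed between the agents, all with 0 members past the threshold by limma. Higher with NP were visceral and primitive endoderm (mean difference 0.39, adjusted p = 6.41e-06), endoplasmic reticulum stress and amino acid response (0.23, adjusted p = 5.44e-06), primed epiblast (0.29, adjusted p = 0.00168), ribosomal proteins (0.08, adjusted p = 0.000972), neural progenitor (0.36, adjusted p = 0.0182), retinoid pathway (0.23, adjusted p = 0.0267) and imprinted genes (0.14, adjusted p = 0.0381). Lower with NP were cholesterol synthesis (-0.36, adjusted p = 2.08e-06), interferon response (-0.51, adjusted p = 0.00398), NRF2 oxidative stress (-0.17, adjusted p = 0.0199) and lipid storage and PPAR targets (-0.20, adjusted p = 0.0283). Adjusted over the list alone, 4 endoplasmic reticulum stress genes and 2 primed epiblast genes were higher and 4 cholesterol synthesis genes lower, and with an estimated correlation the 11 lists had adjusted p values of 0.348 to 0.582. The count of lists was 7 without NP day8 replicate 1. Without BPA day8 replicate 3 the neural progenitor (adjusted p = 0.246) and interferon (0.0617) calls ended. The NRF2 call ended without BPA day8 replicate 1 (0.0702) or 2 (0.0692) or NP day8 replicate 1 (0.0902), and the retinoid call without BPA day8 replicate 1 (0.0702) or NP day8 replicate 1 (0.116). The lipid call ended without BPA day8 replicate 1 (0.059) or 2 (0.119) or NP day8 replicate 1 (0.0715) or 2 (0.0563). The imprinted call ended without BPA day8 replicate 1 (0.059) or 3 (0.156) or NP day8 replicate 1 (0.518) or 2 (0.0575). The arrays of the agents overlapped for the ribosomal protein (exact permutation p = 0.2), imprinted (0.4) and retinoid (0.4) lists. After quantile normalization the ribosomal protein list had an adjusted p of 0.322 and the imprinted list of 0.0644. Without _s_at and _x_at probe sets the imprinted list had an adjusted p of 0.126 and the lipid list of 0.0696.

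Genes of estrogen response and of xenobiotic metabolism did not pass as lists with either agent. In the estrogen response list 1 of 17 members rose and 4 fell with BPA (the same adjusted over the list alone, median -0.17, adjusted p = 0.203), and 1 rose and 3 fell with NP (the same adjusted over the list alone, median 0.04 and mean -0.23, which differ in sign, adjusted p = 0.774). The arrays lay apart for the estrogen response list with both agents (mean 5.76 with BPA, 6.03 with NP and 6.26 on control day8 arrays, exact permutation p = 0.1 for each, the smallest possible). Igfbp4, an insulin-like growth factor binding protein, fell by 2.33 ± 0.27 with BPA and by 2.25 ± 0.27 with NP, and Myb, a transcription factor of progenitor cells, rose by 2.16 ± 0.32 and 1.57 ± 0.32. Over control differentiation 6 members rose and 2 fell (the same adjusted over the list alone, median 0.49, adjusted p = 0.429). Esr1, the estrogen receptor alpha, had means under the background level in each day 8 group (2.38 control, 3.12 BPA, 2.33 NP). In the xenobiotic metabolism list 4 of 17 rose and 2 fell with BPA (the same adjusted over the list alone, median 0.57, and 0.32 with bounds, adjusted p = 0.208), and 3 rose and 2 fell with NP (4 and 2 adjusted over the list alone, median 0.40, and 0.26 with bounds, adjusted p = 0.267). The arrays lay apart for this list with BPA (mean 6.20 against 5.74, exact permutation p = 0.1), and overlapped with NP (exact permutation p = 0.3). Abcb1a, a drug efflux pump, rose by 1.87 ± 0.19 and 1.63 ± 0.19. Cyp1b1, a monooxygenase induced through the aryl hydrocarbon receptor, fell by 0.96 ± 0.21 with BPA, and with NP it was at -0.72 ± 0.21 (adjusted p = 0.0466), a call that ended when any array other than control day8 replicate 3 was left out (adjusted p up to 0.129). It had fallen by 1.27 ± 0.21 over control differentiation. Cyp1a1, another target of that receptor, had risen at least 2.38-fold over control differentiation and was at -0.65 with BPA (adjusted p = 0.201) and -0.55 with NP (adjusted p = 0.313).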

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

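Tests of array scaling, of a mixture of cells, of feeder carry-over, of mesodermal programmes and of shared controls were chosen after the results were seen, while those of RNA quality and of other splits of the arrays were planned.

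Tgfb3 differed between the agents, with NP minus BPA at 3.14 log2 units. The BPA mean lay under the background level, which bounds the rise only at 1.23-fold, and the call ended in 9 of the 12 fits with 1 array left out. Gene lists that differed in the same direct test were primed epiblast (0.29), visceral and primitive endoderm (0.39), neural progenitor (0.36), NRF2 oxidative stress (-0.17), endoplasmic reticulum stress and amino acid response (0.23), cholesterol synthesis (-0.36), lipid storage and PPAR targets (-0.20), ribosomal proteins (0.08), imprinted genes (0.14), interferon response (-0.51) and retinoid pathway (0.23). With an estimated correlation 0 of these lists were called by camera (lowest adjusted p 0.348). The calls of the neural progenitor, NRF2, lipid, imprinted, interferon and retinoid lists also ended when single arrays were left out. Control probe sets outside the gene comparisons also differed from control day8 arrays: the Actb 3' minus 5' difference was higher by 0.265 with BPA and by 0.207 with NP, the Gapdh difference by 0.073 with NP, and the hybridization controls by 0.401 with BPA. In each case the 3 arrays of the agent lay above the 3 control arrays (exact permutation p = 0.1, the smallest possible). The control probe set for the B1 repeat, a repeat family of the mouse genome, moved the other way, by -0.479 with BPA and -0.476 with NP (exact permutation p = 0.1 for each). It had also moved by -0.650 over control differentiation. The hybridization controls also lay apart between NP and BPA (-0.278) and between control day8 and control day0 (-0.174; exact permutation p = 0.1 for each). The Gapdh difference with BPA (0.095) and the hybridization controls with NP (0.123) did not lie apart from control day8 arrays (exact permutation p = 0.4 for each).

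With 3 arrays against 3, 10 splits exist, which are too few for a share under 0.05. Every other split mixes the groups and adds their difference to the spread, so the size of the gap between counts carries no further weight. In control day8 against control day0 the real split gave 6365 genes and the highest other 2, so 1 of 10 splits was as large. For BPA the values were 2906 and 1 (1 of 10), for NP 1852 and 5 (1 of 10), and for NP against BPA 1 and 2 (2 of 10).

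The pluripotency list was higher with both agents than on control day8 arrays, by a camera call that was lost for both with an estimated correlation. The smallest mean change over 3 scalings was 1.88, which argues against array scaling as the whole cause. With the Actb difference as a covariate the change was 1.93 ± 0.34 with BPA and 1.85 ± 0.29 with NP. That covariate lay apart between the arrays of each agent and control day8 arrays, so its slope rests on the small spread within groups. The adjustment therefore cannot settle what part RNA quality had. A mixture of day0-like and control-day8-like cells, with 49.3% to 51.1% of day0 signal on BPA arrays and 32.6% to 51.6% on NP arrays, predicted a median change of visceral endoderm genes of -0.95 and -0.77. The observed values were -0.41 ± 0.14 (SD, n = 3) and 0.03 ± 0.05, and the smallest excess over the prediction on any array was 0.41, which argues against such a mixture as the whole cause. The action of the agents themselves stays open as untested.

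The fibroblast and matrix list was lower with both agents than in both control groups. With an estimated correlation its camera call against control day8 arrays held with NP and was lost with BPA. The 6 members that rose in control culture (Col3a1, Lum, Mmp2, Pdgfrb, Postn and Twist1) had medians of -3.79 with BPA and -3.33 with NP. Fewer carried-over feeder cells predict little fall for members with far less signal at day 0 than at day 8. Lum went from 5.30 to 8.24 and Postn from 8.57 to 11.08, but Col3a1 only from 10.38 to 11.41 and Pdgfrb from 7.74 to 8.73. For Col3a1 and Pdgfrb feeder RNA could supply part of the day 8 signal. The 6 were also chosen by the same control day8 arrays, which lowers their changes in part. Feeder loss therefore stays open as part of the cause. For the 20 members that fell in control culture the medians were -1.55 and -1.06, and there feeder loss and lower expression cannot be told apart, since both predict a fall. With the Actb difference as a covariate the changes were -1.88 ± 0.19 with BPA and -1.76 ± 0.17 with NP, and the limit of that covariate given above applies here too. Of 5 other mesodermal lists 3 fell with both agents (cardiac muscle, vascular endothelium and smooth muscle) and 0 of 6 endodermal, ectodermal and trophoblast lists did by camera, but these calls had been seen before they were counted, and with an estimated correlation only vascular endothelium with NP kept its call (adjusted p = 0.0383), so a fall of mesodermal programmes in general stays open.

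The changes with BPA and with NP correlated across genes. Spread between arrays within groups, passed on through shared controls, gave a covariance of at most 0.192 in 50 simulations, against 0.520 observed. This argues against that spread as the whole cause. An offset common to all control day8 arrays, as from a single culture, was covered neither by the simulations nor by the split controls and stays open. The correlation itself, 0.833, lay within the simulated range of 0.120 to 0.915 and so cannot decide this. What the agents have in common beyond the controls was not tested.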

How the results depend on the processing

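The floor at the background level was chosen after the data were seen, and the other alternatives were planned. For control day8 against control day0 the count of 6365 genes was 10013 over every probe set, 3003 with a fold threshold of 2 and 6175 with the replicate number as a block. For BPA 2906 became 1199 with the fold threshold, 1822 to 2949 with 1 array left out and 2646 with the block. For NP 1852 became 1182 with no filter, 645 with only the compared groups, 764 with the fold threshold, 802 to 1874 with 1 array left out and 1551 with the block. For NP against BPA 1 gene became 4 with no filter, 3 with the mean of probe sets or array weights, 0 with a pseudocount at the 50th percentile, the top 40% filter, only the compared groups, a trend and robust prior, the block or the floor, and 0 to 3 with 1 array left out. The overlap of 1586 became 1014, 564 and 652 with no filter, only the compared groups and the fold threshold, and 730 to 1649 with 1 array left out. With an estimated correlation 0, 0, 2 and 0 lists were called in the 4 comparisons. With the preset correlation, 7 to 16 lists were called for NP against BPA with 1 array left out. Further settings that ended list calls were these: over control differentiation those of retinoid pathway with no filter (adjusted p = 0.0531) or only the compared groups (0.0762), ribosomal proteins without _s_at and _x_at probe sets (0.0576) or with the mean of probe sets (0.0506) and immediate early genes with the top 40% filter (0.0517), with BPA that of Wnt targets with the mean of probe sets (0.101) and of cell cycle with the block (0.05), and between the agents those of lipid storage with no filter (0.14) or the mean of probe sets (0.147), imprinted genes with median centring (0.0559) or the mean of probe sets (0.0603) and retinoid pathway with no filter (0.178). The pluripotency position with BPA was 34.2% after median centring and 26.1% to 30.3% with 1 array left out. The cardiac position with BPA was 29.8% after quantile normalization, 29.4% with a pseudocount at the 50th percentile and 31.8% with the floor. The visceral and primitive endoderm position was 91.8% to 98.5% with BPA and 100.7% to 108.1% with NP with 1 array left out. The correlation of the responses was 0.901 with a pseudocount at the 50th percentile, 0.676 with no filter, 0.918 with the top 40% filter, 0.772 over every probe set, 0.894 with the floor and 0.787 to 0.862 with 1 array left out. It was 0.594, 0.592, 0.586, 0.576, 0.495 and 0.540 with the control arrays split. Among the named genes directions turned only with the mean of probe sets, for Atp2a2 over control differentiation (0.22), Smarcc1 with BPA (0.14) and Uqcrq with NP (-0.04). Among all called genes that setting turned 170, 79 and 32 in the comparisons with a control group, leaving out _s_at and _x_at probe sets turned 39, 25 and 10, and median centring and quantile normalization turned 37 and 5 over control differentiation. With the floor Hbb-bh1 passed with BPA (-3.78, adjusted p = 0.0372) and NP (-4.24, adjusted p = 0.0316), and Afp with NP (1.16, adjusted p = 0.0154). For Afp the floor moved only control day0 values, so its change with NP stayed the same while the spread in the fit shrank. Fewer arrays, fewer genes or a stricter threshold account for part of these shifts by construction, and otherwise the cause was not tested. Of the named genes called, 140 of 162, 104 of 137, 72 of 118 and 0 of 1 kept their call with every array left out in turn, and of the lists 13 of 17, 10 of 12, 12 of 15 and 5 of 11. Residuals of equal replicate numbers correlated by -0.01 to 0.08, so pairing by number was weak at most and the block is given only here. Arrays numbered 3 matched each other best in the comparisons of day 8 groups (0.078, 0.081 and 0.049), so weak pairing is not excluded. Of the calls, 276 over control differentiation, 92 with BPA and 63 with NP had all 3 arrays of a group under the background level.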

Other observations

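All tests in this part were chosen after the data were seen, and 324 gene families named by a shared symbol stem were tested in each direction of the 3 comparisons with a control group. The lists and families were tested with Fisher's exact test, which treats genes as independent. Its p-values are too small where genes vary together. By camera with an estimated correlation the lowest adjusted p of any list was 0.0725 with BPA and 0.0383 with NP.

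With both agents 96 genes lay above both control groups and 95 below, each past the threshold in all 4 comparisons of an agent with a control group. Above were genes of the germ line, with 3 of 14 germ cell genes (Dazl, Sycp3 of the meiotic chromosome axis, and Sohlh2; Fisher's exact test, adjusted p = 0.00554), and of interferon response, with 3 of 20 genes (Psmb8, Irf1 and Bst2; adjusted p = 0.0112). As a list, interferon response passed by camera with BPA but not with NP, whose arrays overlapped control day8 arrays for it. Surface ectoderm (Tfap2c and Cldn4, 2 of 10) and trophoblast (Elf5 and Tfap2c, 2 of 11) passed above the controls and smooth muscle (Acta2 and Mylk, 2 of 12) below them, each with an adjusted p of 0.0461 and resting on 2 genes. The Elf5 calls against control day8 ended, for each agent, when control day0 replicate 2, control day8 replicate 1 or 2 or any BPA or NP array was left out (adjusted p up to 0.143), and the Tfap2c call with NP without control day8 replicate 1 (0.0556) or NP day8 replicate 2 (0.0595). Dazl was at 5.89 on control day0 arrays, 4.15 on control day8, 7.05 with BPA and 6.88 with NP. Aire, a transcriptional regulator known from the thymus, was at 5.02, 4.89, 7.39 and 7.11. Below were 20 of 34 fibroblast and matrix genes (Fisher's exact test, adjusted p = 2.17e-33, too small where these genes vary together). Among them Col5a2 was at 10.16 and 9.12 on control arrays and at 4.76 and 5.07 with BPA and NP, and Dcn, the matrix proteoglycan decorin, at 7.60, 6.25, 3.45 and 3.43. The control day0 signal of such genes may hold feeder RNA, so a level below control day0 arrays may reflect its loss. Collagen genes fell for 15 of 31 members with BPA (adjusted p = 2.6e-05) and 16 of 31 with NP (adjusted p = 2e-09), and 0 rose by limma, under each of the 3 scalings. Over control differentiation 14 of the 31 had risen and 7 had fallen with the deposited values (median 0.97).

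Over control differentiation 19 families had more falling members than Fisher's exact test expects for independent genes, of which 4 are described here. The others were Mrps, Cct, Ddx, Eif, Exosc, Haus, Nop, Psmc, Psmd, Rbm, Snhg, Srsf, Taf, Utp and Wdr, and with NP the Gng and Smad families also passed. Of 47 mitochondrial ribosomal protein genes of the large subunit 31 fell and 2 rose (median -0.56, adjusted p = 5.57e-09), with 30 lower after quantile normalization and 40 after median centring. Of 18 nucleoporin genes 14 fell (median -0.54, adjusted p = 3.11e-05), with 16 and 17 under those scalings, and of 25 RNA polymerase subunit genes 16 fell (median -0.55, adjusted p = 0.000178), with 19 and 24. Of 10 Mcm genes, which include the replicative helicase, 8 fell over control differentiation (median -0.73, adjusted p = 0.00317) and 7 rose with BPA (median 0.49, adjusted p = 0.00993), with 7 and 9 lower and 7 and 7 higher under those scalings.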
